A study of Mus musculus with 8 samples.

How the data were processed

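Mouse cells sorted as Epcr+ Lin− Sca-1+ Kit+ were studied in 8 samples: 1 library each of bone marrow, liver and spleen from a pool of 7 wild-type P2 mice, 1 E19 library, and 2 tubes of Tppp3-CreERT2 LSL-tdTomato P2 pups given tamoxifen at P0, with 2 further hashtag samples whose files held only hashtag reference lists and were not used here. Per the labels, tube 1 held tdTomato-positive cells of pup 1 and tdTomato-negative cells of pup 2, and tube 2 held tdTomato-negative cells of pup 1 and tdTomato-positive cells of pup 2. Hashtags 1 and 3 marked bone marrow and spleen of pup 1, and hashtags 2 and 4 those of pup 2. The labels give the pool, E19 and the pups batches 1, 2 and 3.

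The deposited matrices hold raw UMI counts for 32285 genes. Per the file headers they were made with Cell Ranger 7.0.0 (pooled P2 tissues), 7.1.0 (E19) and 8.0.1 (tubes), while the submitters' processing notes name Cell Ranger 7.0.0 and mm10 for all. The reporter tdTomato is not among the genes counted, so cells were taken as positive or negative from the sort that the labels describe. Gene coordinates are those of mm10/GRCm38 in GENCODE vM21.

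The libraries of P2 bone marrow, liver and spleen, E19, tube 1 and tube 2 held 8061, 6867, 10522, 11323, 2840 and 2838 barcodes with 66765580, 64757553, 86569596, 87254828, 58350172 and 56010320 UMIs, and medians of 6708, 6412, 6265, 6319, 19688 and 18352 UMIs per barcode. Cells with at least 2000 UMIs, at least 1000 genes and at most 10% mitochondrial UMIs were kept. The highest Scrublet scores (scanpy 1.11.5) were removed in each library, as many as 0.8% of barcodes per 1000 barcodes. In the tubes, a cell was assigned to a hashtag where only that hashtag lay over the 99th percentile of its counts in cells led by another hashtag and held at least 3 times the second. This left 6076, 5314, 8277, 9736, 2073 and 1390 cells, 32866 in all, with 33 tdTomato-positive and 1351 negative cells of pup 1 and 39 and 2040 of pup 2. The hashtag rule set aside many cells of the pups, so a second rule was added after the data were seen: the median background of each hashtag was subtracted, and the highest then needed 3 times the second and over 50 counts. It gave 75 and 2221 cells of pup 1 and 82 and 2554 of pup 2. Hashtag calls were checked against sex-linked transcripts of the pups. Xist was seen in 92.5% of negative and 90.9% of positive cells of pup 1, and Y-linked genes in 99.4% and 97.4% of those of pup 2. Xist was also seen in 12.8% of the positive cells of pup 2, which shared a tube with the negative cells of pup 1, against 0.294% of its negative cells, so free RNA or doublets in that small group were not ruled out.

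Cells were clustered together with scanpy and leidenalg 0.10.2 (counts scaled per cell and log-transformed, 2000 variable genes, each gene scaled within its library, 30 principal components, 15 neighbours, resolution 1; seed 1). Each of the 40 clusters was named from marker lists, and 9 stayed unnamed. A marker counted where it was at least 2-fold above the median over all clusters and at 10 CPM or more. A name needed at least 3 markers and 50% of the list, and these thresholds were set after seeing the data. It also needed at least 1 marker of the list among the 10 genes with the largest fold in the cluster. 8 clusters were named HSC-like.

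Shares carry exact 95% binomial intervals and CPM values exact Poisson intervals (scipy 1.17.1), which cover counting error and not the spread between animals. Shares of cells with a Tppp3 UMI and of cells called S or G2/M were computed after thinning each cell to 5000 UMIs, which leaves out cells with fewer (1517, 1622, 2726 and 2518 in P2 bone marrow, liver, spleen and E19, and 53 and 14 negative cells of pups 1 and 2). A phase score was the mean log expression of the S or G2/M list minus that of control genes of like expression. Cells with either score positive were called S or G2/M, and G2/M alone needed the G2/M score positive and higher. Bone marrow and spleen values of 3 sources were compared with 2-sided exact permutation tests of the difference in means, which cannot go below 0.1. These tests regroup all values freely and leave out the pairing of tissues within a source.

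The 3 tested comparisons were fitted to UMI counts summed per source with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, glmQLFit, glmQLFTest, Benjamini-Hochberg threshold 0.05), and fold changes are log2 with standard errors. P2 bone marrow against spleen had 6 sums (pool and tdTomato-negative cells of each pup) with a batch term. tdTomato-positive against negative cells had 4 sums with no further term. Cells with a Tppp3 UMI against cells with none had 8 sums with a batch term, with 3 undetected cells nearest in total UMIs for each detected cell of the same library and tissue, and with Tppp3 itself left out. It used 73 detected cells of the pool, 35 of E19, 23 of pup 1 and 46 of pup 2; among HSC-like cells pup 1 had fewer than 20 and was left out, which gave 6 sums. Sums of 1 source come from the same animals, and after taking out group means their genes deviated alike (correlations of 0.836, 0.686 and 0.821 between bone marrow and spleen of the pool, pup 1 and pup 2; 0.158 between positive and negative cells of the pups; 0.532 to 0.709 in the Tppp3 comparison), so a term for the source (a replicate block) is given where it changed a call. The pool and E19 each count as 1 source, and p-values rest on few animals.

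Lists of genes were tested on the same fits with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. The 25 lists were HSC identity, platelet-biased HSC and megakaryocyte, lymphoid-primed, myeloid progenitor, erythroid, fetal, quiescence-associated, S phase, G2/M phase, interferon response, antigen presentation, immediate early and heat shock, homing and adhesion, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis and TGF-beta targets, and 8 lists of other cell types (hepatocyte, endothelial, macrophage and monocyte, mast cell and basophil, B cell, T, NK and innate lymphoid, stromal, neutrophil). A list's p is adjusted over the lists of 1 comparison.

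Comparisons, lists, cell filters, the hashtag rule and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 CPM and the same direction in every source, up to 4 examples per list, and always Tppp3, Procr, Kit, Ly6a, Hlf, Mecom, Vwf, Itga2b, Flt3, Lin28b, Hmga2 and Igf2bp3. Because the main fits called 0 genes, it was applied to the fits with a source term and with HSC-like cells only, both fixed beforehand, and to the fit with both, which was chosen after seeing the data; not every gene so ranked is printed. Without a test (liver, E19), the rule names up to 10 genes per direction with at least 30 CPM in the higher population and at least 2-fold. Predicted and unnamed genes, mitochondrial and haemoglobin genes and sex-linked genes were left out of the ranking. Percentiles of list medians came from 10000 random lists.

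Alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts or one of 10 CPM, looser cell filters (500 genes, 1000 UMIs, 20%) and stricter ones (2000 genes, 5000 UMIs, 5%), no doublet removal, HSC-like cells only, a hashtag ratio of 10, the source or tube as a block, each source or sum left out, tdTomato by tissue, 10 negative cells per positive cell nearest in UMIs (pup 1 had too few negative HSC-like cells of low depth for a close match), all undetected cells, clustering at resolutions 0.5 and 2 or without cell-cycle genes, and thinning to 2500 UMIs or none. Each fit was tested on counts simulated from the means of each source, with the spread estimated by the fit with a source term. Changes of 2-fold and 4-fold were put between the real groups for randomly chosen genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.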

Results

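Cells from the Epcr+ Lin− Sca-1+ Kit+ gate, which enriches for hematopoietic stem cells (HSCs), were profiled by droplet RNA sequencing in newborn and late fetal mice. At postnatal day 2 (P2), bone marrow, liver and spleen of 7 merged wild-type mice gave 1 library each. Bone marrow and spleen of 2 P2 pups carrying Tppp3-CreERT2 and a tdTomato reporter were hashtagged and sorted as tdTomato-positive or tdTomato-negative. Tamoxifen was given to those pups on the day of birth (P0), so tdTomato marks cells, and their progeny, that expressed Tppp3, a gene for a tubulin-binding protein, at about that time. An embryonic day 19 (E19) library was labelled as bone marrow in its title and as fetal liver in its tissue field, and is called E19 here. The questions addressed were how stem cells of P2 bone marrow and spleen differ, and what sets apart cells that express or expressed Tppp3.

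The share of HSC-like cells, called from clusters with high Mecom, Hlf and other HSC markers, ranged from 3.07% (95% interval 2.62 to 3.57) in P2 liver to 98.5% (97.9 to 99.01) in the tdTomato-negative cells of pup 2. In liver it was 4.67% when the clustering resolution was doubled. It was 22.7% (21.6 to 23.8) of 6076 cells in pooled bone marrow and 15.1% (14.3 to 15.9) of 8277 in pooled spleen. At E19 it was 87.5% (86.8 to 88.1) of 9736 cells and in pup 1 70.5% (68.0 to 73.0) of 1351. Pooled P2 tissues held B cell-like cells (16.5%, 29.2% and 22.2% in bone marrow, liver and spleen), erythroid-like cells (10.9%, 11.4% and 23.3%) and myeloid progenitor-like cells (14.4%, 18.4% and 7.77%), although the gate selects against lineage-positive cells. Neutrophil-like cells made up 34.8% of tdTomato-negative cells in pup 1 bone marrow and 11.1% in its spleen. Their difference of 23.6 points stayed with resolution doubled or without cell-cycle genes. It was 0 with resolution halved, where unnamed cells of pup 1 differed by 32.9 points. One cluster with HSC markers (Mecom, Hlf) and myeloid markers (Ctsg and Mpo, which encode a granule protease and a peroxidase) stayed unnamed. It held 17.1% (16.1 to 18.1) of pooled bone marrow cells and 11.1% of pooled spleen cells, against 0.0514% at E19. HSC-like cells of the pool, of E19 and of tube 2 fell largely into different clusters. The bone marrow minus spleen difference in HSC-like share was 7.61 points in the pool, −31.7 in pup 1 and 0.0596 in pup 2 (exact permutation p = 1). This test does not pair the tissues of a source, and with 3 against 3 populations no exact p can fall under 0.1.

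**Figure D1:**
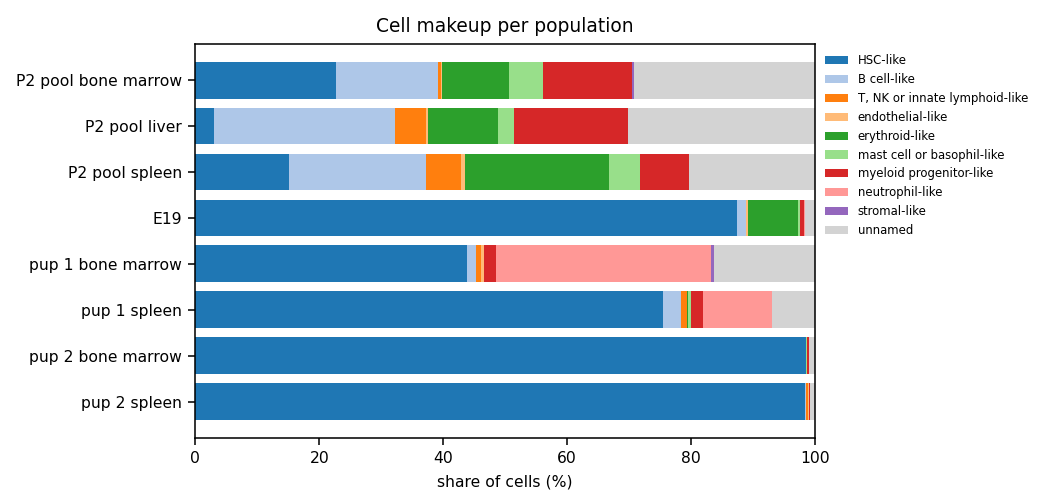
Share of cells (%) per named type in each P2 population and at E19, with tdTomato-negative cells for the pups and 1 bar per population. HSC-like cells were 22.7% of pooled bone marrow, 3.07% of pooled liver and 98.5% of pup 2 cells.

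Tppp3 (chromosome 8, 105467493 to 105471526, minus strand, mm10/GRCm38) was seen in few cells. With every cell thinned to 5000 UMIs, a Tppp3 UMI was present in 44 of 10830 HSC-like cells (0.406%, 0.295 to 0.545), whose median depth was 8128 UMIs before thinning. As a measure of free RNA, it was present in 0 of 1604 B cell-like cells (exact upper limit 0.23%, median depth 8083.5) and 1 of 2537 myeloid progenitor-like cells (0.0394%, 0.000998 to 0.219, median depth 17891). Of the B cell-like cells, 97 were of E19 and 1 was of pup 2, so this measure says little on those sources. Over every class but HSC-like, 24 of 13582 cells had a Tppp3 UMI (0.177%, 0.113 to 0.263, median depth 11696). Among these were 5 of 3754 erythroid-like cells (0.133%) and 16 of 4567 cells in unnamed clusters (0.350%, 0.200 to 0.568). The interval of the unnamed cells overlapped that of HSC-like cells. Among HSC-like cells the Tppp3 share was 3.42% (1.12 to 7.81) in P2 liver (5 of 146 cells), 0.767% in pooled bone marrow and 0.648% in pooled spleen. It was 0.501% and 0.420% in tdTomato-negative cells of pups 2 and 1, assigned by hashtag, and 0.229% (0.125 to 0.384) at E19. In pup 1 the share was higher outside the HSC-like class, at 6 of 346 cells (1.73%, 0.639 to 3.74). All 6 lay in unnamed clusters (5.50% of 109 cells, 2.05 to 11.6, median depth 19110, against 25995 in HSC-like cells), while 0 of 155 neutrophil-like cells had one, so in pup 1 the HSC-like share did not stand above that of other cells. At E19 the HSC-like interval overlapped that of other cells (1 of 1102, 0.0907%, 0.0023 to 0.505). In pup 2, 0 of 29 other cells had a Tppp3 UMI (exact upper limit 11.9%), too few to compare. In pooled bone marrow the intervals overlapped (0.282 to 1.66 against 0.0745 to 0.381). The HSC-like interval lay above that of other cells in pooled liver (other cells 0.0794 to 0.406) and spleen (0.211 or more against 0.0129 to 0.183). Among tdTomato-positive cells of all types, 0 of 29 in pup 1 and 0 of 39 in pup 2 had a Tppp3 UMI, with exact upper limits of 11.9% and 9.03%. The bone marrow minus spleen difference over all cells was 0.141, 0.375 and −0.0928 points in the pool, pup 1 and pup 2 (exact permutation p = 0.7). At 2500 UMIs per cell these differences were 0.118, −0.351 and −0.289 points, so that of pup 1 changed sign. Without thinning they were 0.248, 0.240 and −0.120.

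Calls of S or G2/M phase from cell-cycle transcripts, at 5000 UMIs per cell, covered 71.5% (70.1 to 72.8) of pooled bone marrow cells and 73.0% (71.8 to 74.2) of pooled spleen cells. They covered 57.6% (56.0 to 59.2) of liver cells and 42.1% (40.9 to 43.2) of E19 cells. Among HSC-like cells the shares were 39.0% in pooled bone marrow, 31.2% in pooled spleen, 19.9% (13.7 to 27.3) in liver and 35.8% at E19, and 63.0% and 57.3% in tdTomato-negative cells of pups 1 and 2. G2/M calls alone covered 0.639%, 1.68% and 0.685% of HSC-like cells in pooled bone marrow, spleen and liver, against 21.5% (20.5 to 22.6) at E19 and 35.9% and 30.4% in pups 1 and 2. The HSC-like class of the pool thus held few G2/M cells, and the unnamed cluster with HSC markers is not counted in it, so these shares do not compare like classes. Phase calls also read free RNA and alone do not show that cells divide. Bone marrow minus spleen differences over all cells were −1.51, −6.69 and −13.3 points in the pool, pup 1 and pup 2 (exact permutation p = 0.4). In the pool the sign changed with depth, to 6.71 points at 2500 UMIs per cell and 11.3 without thinning, while both pups stayed below 0.

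HSC-like cells of P2 bone marrow had more transcripts of the immediate early transcription factors Fos, Jun and Junb than those of spleen. Cells were summed per animal source (pool, pup 1, pup 2) and fitted with a term for the source, a fit chosen after the data were seen. Fos was higher by 2.15 ± 0.246 on the log2 scale (28.3 against 5.26 CPM, UMI counts scaled by the total of each sum, edgeR adjusted p = 0.00447) in 3 of 3 sources. Jun was higher by 1.06 (148 against 67.7 CPM, adjusted p = 0.000749) and Junb by 0.62 ± 0.0972 (adjusted p = 0.0496). Fosb, whose product dimerizes with Jun, was higher by 3.33 ± 0.298 (adjusted p = 0.000749). Ppp1r15a, which encodes a stress-induced phosphatase subunit, and Sik1, a kinase gene, were higher by 0.77 ± 0.113 and 0.62 ± 0.0961 (adjusted p = 0.0464 and 0.0496). Cox4i2, which encodes a subunit of cytochrome c oxidase, was lower at −0.87 ± 0.132 (15.3 against 28.1 CPM, adjusted p = 0.0496). These were the 7 genes called of 13533, with 1095 at an unadjusted p under 0.05. On simulated data this fit recovered 100 of 100 planted 2-fold and 100 of 100 4-fold changes and made 14 false calls. Without the source term these were 98, 100 and 1. The false calls came beside many true ones, so their number does not carry over to the 7 genes. With a batch term in place of the source, edgeR called 0 genes in HSC-like cells (411 at an unadjusted p under 0.05) and 0 of 14966 over all cells (274), where DESeq2 called 9 higher and 3 lower (430). Over all cells the source term gave 1 gene, Iglc1, an immunoglobulin light-chain gene, at −3.58 ± 0.178 (3.97 against 44.4 CPM, adjusted p = 0.0142). With the batch term, leaving out pup 1 gave 11 higher and 30 lower genes over all cells, and leaving out pup 2 gave 4 and 6. Leaving out the pool, which leaves 1 batch, gave 0 over all cells (91 at an unadjusted p under 0.05) and 0 in HSC-like cells (287).

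**Figure D2:**
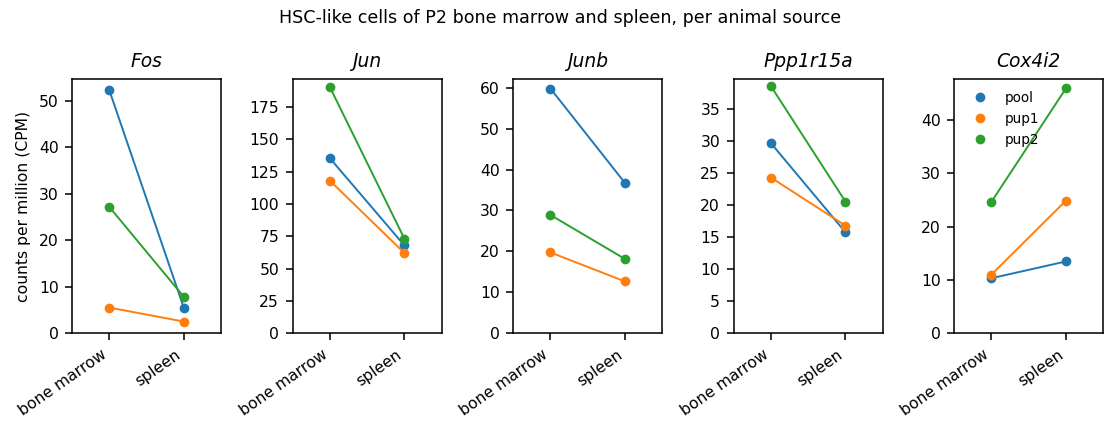
Expression (CPM) of Fos, Jun, Junb, Ppp1r15a and Cox4i2 in the summed HSC-like cells of bone marrow and spleen, where each point is 1 sum and lines join sums of the same animals. Fos had a mean of 28.3 CPM in bone marrow and 5.26 in spleen.

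No gene of HSC identity was called between bone marrow and spleen in the HSC-like cells with a term for the source. The HSC transcription factor genes Hlf and Mecom were at 0.14 ± 0.0982 and 0.02 ± 0.0978, Procr, which encodes Epcr, at 0.11, Kit at 0.03 and Ly6a (Sca-1) at −0.01. The platelet genes Vwf (0.19 ± 0.212) and Itga2b (−0.06), the lymphoid-primed receptor gene Flt3 (0.22 ± 0.0859), Tppp3 (0.25 ± 0.379) and the fetal genes Lin28b (−0.12), Hmga2 (0.16) and Igf2bp3 (−0.03) were not called either, and the lowest edgeR adjusted p among all these was 0.545.

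Among lists of genes in HSC-like cells with the batch term, immediate early and heat shock genes were higher in bone marrow (median log2 fold change 0.36, 13 of 17 genes higher, 0 called over all genes and 9 adjusted over the list alone). Their camera adjusted p was 5.75e-18, and 0.583 with an estimated correlation. Oxidative phosphorylation genes were lower (median −0.23, 0 of 21 higher, camera adjusted p = 5.98e-10, adjusted p = 0.583 with an estimated correlation), and with the source term 12 of them were lower, adjusted over the list alone. Quiescence-associated genes (0.18, 13 of 15 higher, adjusted p = 1.72e-06) and myeloid progenitor genes (0.25, 8 of 11, adjusted p = 0.00119) were higher, with adjusted p = 0.532 and 0.583 with an estimated correlation. Over all cells, erythroid genes (median −0.95, 1 of 15 higher, adjusted p = 2.12e-05), S phase genes (−0.17, 1 of 42, adjusted p = 4.52e-09), T, NK and innate lymphoid genes (−1.78, 2 of 10, adjusted p = 0.000143) and mast cell and basophil genes (−0.48, 3 of 8, adjusted p = 0.0291) were lower. With an estimated correlation, adjusted p = 0.493 for each of these, and with the source term mast cell and basophil genes were not called (adjusted p = 0.0903). Stromal genes (1.99, 5 of 5 higher, adjusted p = 0.00127), TGF-beta and SMAD targets (0.36, 11 of 13, adjusted p = 0.00824) and fetal genes (0.28, 11 of 14, adjusted p = 0.000661) were higher, again with adjusted p = 0.493 with an estimated correlation. B cell genes (1.00, 7 of 10, adjusted p = 0.0267, and 0.706 with an estimated correlation) and lymphoid-primed genes (0.21, 10 of 15, adjusted p = 0.00478, and 0.464 with an estimated correlation) were higher too. The antigen presentation list was called lower (adjusted p = 0.00478, and 0.464 with an estimated correlation) with a mean of −0.47, although its median was near 0 and 7 of 15 genes were higher.

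Over all cells, HSC identity genes (median 0.07, 12 of 20 higher in bone marrow, camera adjusted p = 0.296), platelet-biased HSC and megakaryocyte genes (−0.06, adjusted p = 0.0725), G2/M genes (−0.03, adjusted p = 0.1) and interferon response genes (0.06, adjusted p = 0.889) were not called. Lists for homing and adhesion (median 0.04 with a mean below 0, adjusted p = 0.68), hypoxia and glycolysis (0.12, adjusted p = 0.355), hepatocytes (0.02, adjusted p = 0.438) and endothelium (0.22, adjusted p = 0.498) were not called. Nor were macrophage and monocyte genes (0.31, adjusted p = 0.972) or neutrophil genes (1.18, 6 of 6 higher, adjusted p = 0.398), although with the source term neutrophil genes were called higher (0.99, adjusted p = 4.42e-15, and 0.275 with an estimated correlation). The fry test called 1 list over all cells, immediate early and heat shock (adjusted p = 0.0372), and with the source term also lymphoid-primed genes (adjusted p = 0.0135).

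tdTomato-positive HSC-like cells had more Ahnak, Pde3a and Meg3 and fewer transcripts of mitotic genes than tdTomato-negative HSC-like cells, in both pups. Ahnak, which encodes a giant scaffold protein, was higher by 1.55 ± 0.174 (153 against 51.3 CPM, edgeR adjusted p = 0.00901). The phosphodiesterase gene Pde3a was higher by 2.26 ± 0.308 (27.7 against 5.25 CPM, adjusted p = 0.0142) and Meg3, an imprinted long noncoding RNA expressed in long-term HSCs, by 1.80 ± 0.263 (64.7 against 16.3 CPM, adjusted p = 0.0152). Ube2c, which encodes a ubiquitin-conjugating enzyme of mitotic exit, was at −2.31 ± 0.165 (45.3 against 224 CPM, adjusted p = 0.000643). Cenpf, a kinetochore gene, was at −2.09 ± 0.180 (62.9 against 267 CPM, adjusted p = 0.00202) and the mitotic kinase gene Plk1 at −2.57 ± 0.368 (7.36 against 48.9 CPM, adjusted p = 0.0152). Of 13559 genes, 17 were higher and 57 lower in these 4 sums (2 pups, positive and negative), with 1612 at an unadjusted p under 0.05. In each pup the positive and negative cells came from different tubes and lay largely in different clusters: 2 HSC-like clusters almost wholly of tube 2 held 98.5% of negative and 0 of 28 positive HSC-like cells of pup 1, and 0 of 2010 negative and 92.1% of positive ones of pup 2. Further rises included Pirb (1.75), Adgre5 and Cd68 (1.40), surface or lysosomal genes of myeloid cells, and Itsn1, Adam22 (1.13), Tmtc2 (1.04) and Col4a2 (0.98). Further falls included the cell-cycle genes Cdkn3 (−2.99), Kif2c (−1.97), Ccnb1 (−1.86), Kif22 (−1.86), Hmmr (−1.81) and Cdc20 (−1.79). With hashtags corrected for background, a rule chosen after the data were seen, edgeR called 0 genes in HSC-like cells (783 at an unadjusted p under 0.05), and with a term for the pup 138 higher and 290 lower. With the fixed hashtag rule and the negative HSC-like cells nearest in total UMIs, it called 0 (237 at an unadjusted p under 0.05), and with a term for the pup 5 higher and 4 lower. This match held in pup 2 (median 18096.5 against 18150.5 UMIs) but not in pup 1 (13244.5 against 17114). Over all cells it called 0 of 14034 genes (1100 at an unadjusted p under 0.05), while DESeq2 called 40 higher and 74 lower, and edgeR with a term for the pup 92 higher and 234 lower. Leaving out the negative cells of pup 1 gave 55 higher and 61 lower genes over all cells, leaving out those of pup 2 gave 59 and 326, and leaving out the positive cells of either pup gave 0 by edgeR (1345 and 1362 at an unadjusted p under 0.05). In each of these fits 1 arm is a lone sum, assumed to vary like the other arm. Xist, which pup 1 expressed, had a UMI in 5 of 39 tdTomato-positive cells of pup 2 (12.8%) against 0.294% of its negative cells.

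**Figure D3:**
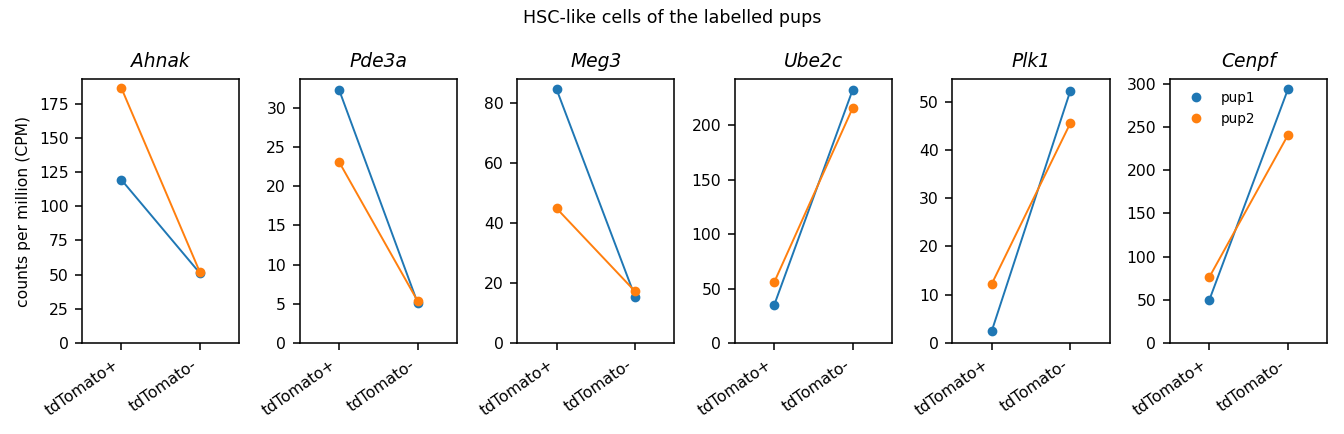
Expression (CPM) of Ahnak, Pde3a, Meg3, Ube2c, Plk1 and Cenpf in summed tdTomato-positive and tdTomato-negative HSC-like cells, where each point is 1 sum and lines join the sums of 1 pup. Ube2c had a mean of 45.3 CPM in positive and 224 CPM in negative cells.

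With a term for the pup, chosen after the data were seen for HSC-like cells, 103 genes were higher and 272 lower in tdTomato-positive HSC-like cells (1535 at an unadjusted p under 0.05). HSC transcription factor genes were then called higher: Mecom by 0.41 ± 0.0783 (edgeR adjusted p = 1.75e-05), Hlf by 0.38 ± 0.0836 (adjusted p = 0.000612) and Mllt3 by 0.63 ± 0.0959 (adjusted p = 1.41e-08). Without the term Mecom (adjusted p = 0.134) and Hlf (adjusted p = 0.32) were not called. Fos (2.72 ± 0.298), the imprinted growth factor gene Igf2 (2.25 ± 0.409), the nuclear lamina gene Lmna (1.89 ± 0.313) and the quiescence factor gene Klf2 (1.84) were higher. Cd48, a surface protein gene that is on in progenitors and low in HSCs (−0.86 ± 0.186, adjusted p = 0.000418), and Mpo (−1.08 ± 0.318, adjusted p = 0.0296) were lower. With the pup term, 4 sums leave little to estimate the spread between pups, so these p-values rest largely on variation estimated over all genes. The same fit called 9 genes with negative cells nearest in UMIs, 428 with corrected hashtags, and 0 with both. Without the term, Procr (0.45 ± 0.214), Vwf (0.90 ± 0.513), Kit (0.05), Ly6a (0.32), Itga2b (−0.02), Flt3 (−0.19), Lin28b (−0.25), Hmga2 (0.12), Igf2bp3 (−0.35 ± 0.106) and Tppp3 itself (1.02 ± 1.26) were not called.

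G2/M genes had a median of −1.07 in tdTomato-positive HSC-like cells (0 of 52 higher, 23 lower over all genes and 49 adjusted over the list alone, camera adjusted p = 2.91e-118, and 0.385 with an estimated correlation). Positive cells of all types had fewer UMIs than negative ones (median 12930 against 23394 in pup 1, and 18070 against 20930 in pup 2). With the pup term, the G2/M median was −0.35 with the negative cells nearest in total UMIs (a match that held in pup 2 only) and −0.28 with hashtags corrected for background. S or G2/M calls covered 29.6% (13.8 to 50.2) of 27 positive and 63.0% of negative HSC-like cells in pup 1, and 42.1% (26.3 to 59.2) of 38 and 57.3% in pup 2. With corrected hashtags these shares were 35.7% against 51.2% in pup 1 and 53.2% against 54.7% in pup 2.

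HSC identity genes were higher as a list in tdTomato-positive HSC-like cells (median 0.32, 19 of 20 higher, 0 called over all genes and 5 adjusted over the list alone, camera adjusted p = 3.86e-07). So were platelet-biased HSC and megakaryocyte genes (0.15, 16 of 20, adjusted p = 0.00564), fetal genes (0.48, 10 of 13, adjusted p = 2.74e-06), quiescence genes (0.64, 10 of 15, adjusted p = 0.000188) and macrophage and monocyte genes (0.32, 4 of 5, adjusted p = 0.024). With an estimated correlation, adjusted p = 0.488 for each of these 5 lists. Immediate early and heat shock genes were higher (0.61, 12 of 17, adjusted p = 0.000992, and 0.616 with an estimated correlation). S phase genes (−0.25, 3 of 42 higher, adjusted p = 3.38e-08) and oxidative phosphorylation genes (−0.30, 0 of 21, adjusted p = 1.83e-08) were lower, with adjusted p = 0.385 and 0.564 with an estimated correlation. Lymphoid-primed (−0.02, adjusted p = 0.971), myeloid progenitor (−0.49, adjusted p = 0.0967), erythroid (0.34, adjusted p = 0.263), interferon (0.09, adjusted p = 0.335), cholesterol synthesis (0.18, adjusted p = 0.335) and TGF-beta (−0.04, adjusted p = 0.159) lists were not called. Neutrophil genes had a median of 0.72 (7 of 7 higher, adjusted p = 0.159) and, with the pup term, 1.27 (adjusted p = 1.52e-05, and 0.578 with an estimated correlation), with the alarmin genes S100a9 and S100a8 at 1.72 and 1.48. Over all cells, erythroid genes had a median of 2.70 (14 of 14 higher, adjusted p = 9.82e-06) and myeloid progenitor genes −2.13 (0 of 14, adjusted p = 4.42e-06), both with adjusted p = 0.727 with an estimated correlation. Elane, a neutrophil protease gene, had 0 counts in positive cells and 205 CPM in negative cells of pup 1, which held neutrophil-like cells.

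HSC-like cells with a Tppp3 UMI had more Lmna, Ahnak and Vim than HSC-like cells without one, in 3 of 3 sources (pool, E19, pup 2). Lmna, which encodes the nuclear lamins A and C (chromosome 3, 88480147 to 88509956, minus strand), was higher by 3.55 ± 0.230 (181 against 13.7 CPM, edgeR adjusted p = 6.9e-50). Ahnak (chromosome 19, 8989284 to 9076914, plus strand) was higher by 2.63 ± 0.174 (255 against 38.6 CPM, adjusted p = 8.18e-48) and Vim, the intermediate filament vimentin, by 1.66 ± 0.0952 (1512 against 410.0 CPM, adjusted p = 2.81e-63). S100a6, a calcium-binding protein gene, was higher by 1.49 ± 0.163 (231 against 82.5 CPM, adjusted p = 7.19e-17), and Mecom by 0.38 ± 0.0803 (1456 against 1028 CPM, adjusted p = 0.000618). Cd48 (−1.02 ± 0.202, adjusted p = 0.000159), Mpo (−1.11 ± 0.293, adjusted p = 0.0205) and the cell-cycle gene Cks2 (−0.80 ± 0.162, adjusted p = 0.000257) were lower. Shares of cells with a UMI were counted over all undetected HSC-like cells, without the match in UMIs. At E19 detected cells were deeper (median 6821 UMIs, against 6075 over all HSC-like cells). A Lmna UMI was seen in 58.1% of Tppp3-detected and 9.86% of undetected HSC-like cells of the pool and in 63.0% and 15.8% in pup 2, but in 6.06% and 4.89% at E19. For Ahnak the shares were 64.5% and 15.4% in the pool, 82.6% and 38.8% in pup 2, and 21.2% and 7.18% at E19. In pup 1, whose 13 Tppp3-detected HSC-like cells were too few for a sum, the shares were 30.8% and 16.9% for Lmna, 76.9% and 52.3% for Ahnak, and for S100a6 61.5% and 62.0%. Of 8417 genes, 57 were higher and 29 lower in these 6 sums of cells matched in UMIs (690 at an unadjusted p under 0.05), which held 31, 33 and 46 Tppp3-detected cells of the pool, E19 and pup 2. These 6 sums leave little to estimate the spread between the 3 sources. The very small p-values therefore rest largely on variation estimated over all genes and do not measure that spread.

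**Figure D4:**
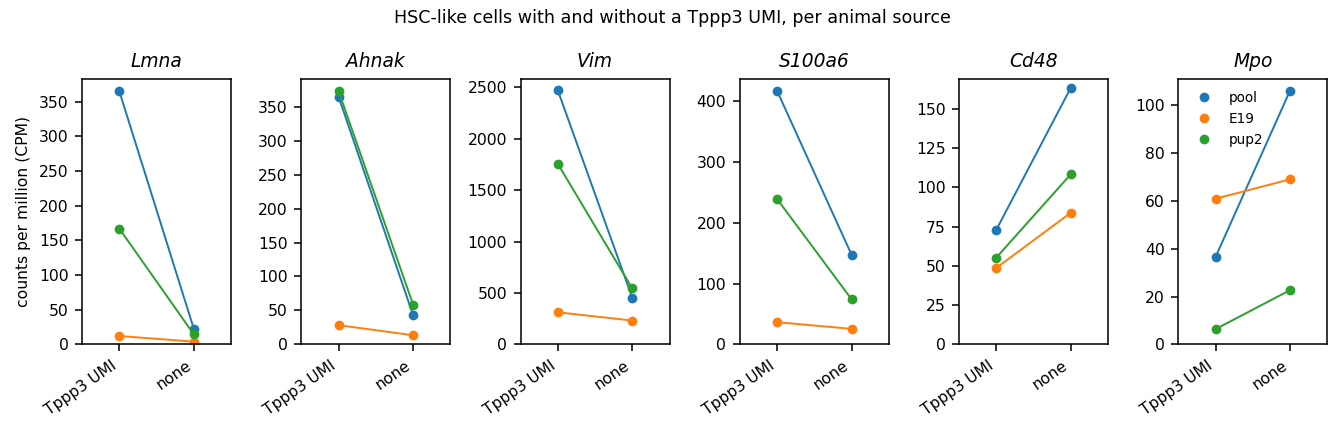
Expression (CPM) of Lmna, Ahnak, Vim, S100a6, Cd48 and Mpo in summed HSC-like cells with and without a Tppp3 UMI, where each point is 1 sum and lines join sums of 1 source. Lmna had a mean of 181 CPM in detected and 13.7 CPM in undetected cells.

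Other genes higher in Tppp3-detected HSC-like cells were Rfx2, a ciliogenic transcription factor gene, Myadm (1.62 ± 0.333), Hdac9 (1.55), Pdlim1 (1.46), Col18a1 (1.35), the platelet genes Plek (1.19 ± 0.242) and Cd9, the adhesion receptor gene Cd44 (0.65 ± 0.139), and Meg3 (1.21 ± 0.263). Of the cholesterol synthesis genes, Idi1 was higher by 1.37 ± 0.227 (edgeR adjusted p = 1.14e-06), Fdps by 1.17 ± 0.212 (adjusted p = 1.93e-05) and Hmgcs1 by 1.21 ± 0.244 (adjusted p = 0.000224). Their list had a median of 0.72 (13 of 13 higher, 3 called over all genes and 10 adjusted over the list alone, camera adjusted p = 5.44e-14). HSC identity genes (0.15, 13 of 18, adjusted p = 0.00233) and platelet-biased HSC and megakaryocyte genes (0.19, 8 of 10, 2 over all genes and 3 adjusted over the list alone, adjusted p = 0.000701) were higher, while myeloid progenitor genes were lower (−0.41, 1 of 5 higher, adjusted p = 0.000286). With an estimated correlation, adjusted p = 0.447 for each of these 4 lists. G2/M genes were lower (−0.37, 4 of 50 higher, 4 lower over all genes and 16 adjusted over the list alone, adjusted p = 1.68e-19, 0.166 with an estimated correlation and 0.0357 with fry). Oxidative phosphorylation genes (−0.14, 4 of 21 higher, adjusted p = 0.00108, and 0.497 with an estimated correlation) and antigen presentation genes (−0.22, 1 of 9, adjusted p = 0.039, 0.447 with an estimated correlation and 0.0145 with fry) were lower. The S phase histone genes Hist1h2ab (−1.29) and Hist1h1b (−0.74 ± 0.125) were lower, while the S phase list was not called (−0.02, adjusted p = 0.778). Lymphoid-primed (−0.09, adjusted p = 0.544), fetal (0.25, adjusted p = 0.115), quiescence (0.12, adjusted p = 0.195), interferon (−0.12, adjusted p = 0.115), immediate early (0.12, adjusted p = 0.17), homing (0.01, adjusted p = 0.981) and hypoxia (0.01, adjusted p = 0.981) lists were not called.

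Among genes always given, Vwf (1.41 ± 0.461, edgeR adjusted p = 0.135), Hlf (0.14 ± 0.0989), Procr (0.14), Kit (−0.26), Ly6a (−0.03), Flt3 (−0.09), Lin28b (−0.38), Hmga2 (−0.14) and Igf2bp3 (−0.11) did not pass the test between Tppp3-detected and undetected HSC-like cells, and Itga2b was too low to be tested. Over all cells of 4 sources, edgeR with the batch term called 0 of 9004 genes (431 at an unadjusted p under 0.05), and DESeq2 called 6 higher and 8 lower. With a term for the source it called 24 higher and 21 lower, with Ahnak (2.39 ± 0.170) and Meg3 higher and the B cell genes Cd79a (−2.37) and Ebf1 (−1.95) lower. With the batch term, leaving out pup 1 gave 25 higher and 27 lower genes, leaving out pup 2 gave 6 and 12, and leaving out E19 gave 1 and 0. Leaving out the pool gave 0 genes (279 at an unadjusted p under 0.05).

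Summed over all cells within the gate, P2 liver differed from both other pooled P2 tissues in transcripts of several cell types. Camp, an antimicrobial gene of neutrophils, had 150.0 CPM (146.9 to 153.2) in liver against 3.64 in the nearest other tissue, and S100a9 had 690 (683 to 697) against 69.0. Gzma and Ccl5, genes of cytotoxic lymphocytes, had 265 against 22.1 and 228 against 17.4 CPM. Clec9a and Cadm1, genes of cross-presenting dendritic cells, had 46.1 against 4.87 and 134 against 16.6 CPM. HSC genes were lower, with Mecom at 43.8 (42.1 to 45.5) against 148, Hlf at 27.1 against 88.1 and Angpt1, a ligand made by HSCs, at 80.7 against 272. The HSC identity list had medians of −1.51 against bone marrow and −1.16 against spleen. Hepatocyte genes had 3.29 and 3.42, neutrophil genes 3.30 and 3.98, and T, NK and innate lymphoid genes 2.93 and 1.10. Of the 104 genes that differed at least 2-fold from both tissues, 89 were higher. Among the 163 HSC-like liver cells 12 genes did, 11 of them higher, 0 of them shared with the 104, and Mecom was at 1074 CPM against 842 in the nearest tissue. In those cells Ighm, an immunoglobulin gene, had 46.4 against 14.4 CPM, and interferon response genes had medians of 0.39 and 0.37 (21 of 23 higher). Markers of other cells were higher in them too, with medians of 0.37 and 0.47 for lymphoid-primed genes (9 of 10 higher) and 2.40 and 2.29 for the 2 neutrophil genes measured, while erythroid genes were lower (−0.54 and −0.18, with 1 of 6 and 2 of 7 higher). No cluster was named hepatocyte-like, and free RNA was not told apart from cells as a source of these transcripts. Liver is 1 library, so these are values without a test.

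E19 HSC-like cells had more transcripts of Plk2, Hes1 and Nr4a1 and fewer of Ahnak, S100a6 and Anxa1 than HSC-like cells of every P2 population. Plk2, a stress-responsive kinase gene, had 34.5 CPM (33.0 to 36.1) against 4.16 (2.86 to 5.84) in the nearest population, and Hes1, a Notch target, 45.4 against 9.88. The orphan nuclear receptor gene Nr4a1 had 60.4 against 16.7 CPM and the fetal RNA-binding protein gene Igf2bp1 33.8 against 10.4. Ahnak had 11.8 CPM (10.9 to 12.7) against 37.8, S100a6 22.0 against 50.2, Anxa1 (annexin A1) 19.4 against 59.6 and H2-D1, a class I antigen-presenting gene, 130 against 282. Ly6a had 24.3 CPM against 46.6 or more, and Mecom 1512 against at most 1134. Against the 7 P2 populations, interferon response genes had medians from −0.62 to −1.16 and antigen presentation genes from −0.69 to −1.06. Fetal genes had 0.25 to 0.90, quiescence genes 0.39 to 0.89 and immediate early genes 0.25 to 1.06. Erythroid genes moved more than these lists against most populations (0.68 to 4.61, 6 or 7 genes measured). Over all cells the interferon medians had the opposite sign against pooled bone marrow, liver and spleen (0.20, 0.14 and 0.27), and the quiescence median against pup 1 bone marrow was −0.33. G2/M genes had 1.09 to 1.26 against the HSC-like cells of the pooled tissues, which held few cells called G2/M, and −0.81 to −1.29 against those of the pups. Over all cells the G2/M medians against pooled bone marrow, liver and spleen had the opposite sign (−0.59, −0.43 and −0.52, with 1, 4 and 3 of 52 genes higher). In all, 47 genes over all cells (30 higher) and 41 in HSC-like cells (32 higher) differed at least 2-fold from every P2 population. E19 is 1 library of its own batch with labels that name 2 tissues, so age, tissue and batch cannot be told apart and no test was run.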

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

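The random draws of undetected cells, the fits with HSC-like cells only and the fits with a source term over all cells were set before their results were seen, and the other tests here, among them the counts of splits, were chosen after it.

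With hashtags corrected for background, 3 of 12360 genes differed between bone marrow and spleen in their tdTomato-positive against negative contrast (edgeR interaction over 8 sums, 624 at an unadjusted p under 0.05): Stfa2l1, Cstdc4 and Stfa3, which encode cysteine protease inhibitors of neutrophils. With the fixed hashtag rule 0 of 10749 did (360 unadjusted). Bone marrow minus spleen differences had one sign in the pool and the other in both pups for mast cell or basophil-like cells (0.308 points in the pool, −0.526 and −0.0609 in pups 1 and 2), for HSC-like cells with a Tppp3 UMI (0.120, −0.465 and −0.0937) and for HSC-like cells called S or G2/M (7.78, −1.18 and −13.8). These opposite signs were not tested. The 4 sums of the tdTomato comparison allow 3 splits, too few for a share under 0.05. In HSC-like cells the real split called 74 genes and the highest other 45 (pup 1 against pup 2), and over all cells 0 and 307 (also pup 1 against pup 2), which points to a difference between the pups. With the pup term the real split called 375 against 8 in the split by tube, and over all cells 326 against 74. No group of deposited samples held 4 to 10, so no sample was tested for lying apart from its group, and neither was any sum.

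The G2/M genes were lower in tdTomato-positive cells, with a median of −0.89 over all cells. Cells outside the HSC-like clusters do not account for it, since the median was −1.06 in HSC-like cells with the pup term. Positive and negative cells of each pup lay largely in different HSC-like clusters. A different mix of cells within that class was therefore not excluded. The hashtag rule may account for much of it, since the median was −0.28 with hashtags corrected for background. The median was −0.35 with the negative cells nearest in total UMIs. That match held in pup 2 but not in pup 1 (median 13244.5 against 17114 UMIs), so it evened out depth only in part. It also cannot tell depth from phase if total UMIs vary with phase. Thinning to 5000 UMIs evened out depth in every cell. S or G2/M calls then covered 29.6% (13.8 to 50.2) of positive and 63.0% (59.9 to 66.1) of negative HSC-like cells in pup 1. In pup 2 they covered 42.1% (26.3 to 59.2) and 57.3% (55.1 to 59.5). At even depth the gap stayed in pup 1 and the intervals overlapped in pup 2, so the part due to depth was not settled. A slower cycle of the labelled lineage stays open and was not tested apart from depth and the hashtag rule.

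Lmna, Ahnak and Vim were higher in Tppp3-detected HSC-like cells. Other cell types or doublets would dilute HSC identity genes, whose lower quartile of log2 fold changes was −0.00347 and whose median was 0.15. The cells came only from HSC-like clusters, named from several of the same genes, so strong dilution was removed beforehand. A smaller share of other cells or doublets was therefore not excluded. Tppp3 UMIs from free RNA would mark random cells, but 0 of 20 random draws of undetected cells called as many as 86 genes (highest 13). Another hypothesis, not told apart from such cells, is that Tppp3 is expressed in a subset of HSC-like cells with high Lmna, Ahnak and Vim. At E19 the share of cells with Lmna hardly differed (6.06% against 4.89%), while that with Ahnak did (21.2% against 7.18%). Both were counted over all undetected cells, without the match in UMIs. Splits of the 6 sums number 10, too few for a share under 0.05: the real split called 86 genes and the highest other 23, and 1 split (the real one) reached 86. Over all cells the real split of 8 sums called 0 genes, so that all 34 splits call as many by construction and the count says nothing about chance. The highest other called 295, with the pool and 1 pup against E19 and the other pup, which points to the structure of sources. With the source term the real split called 45 genes against at most 16 in the other splits that part every pair.

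Immediate early genes were higher in bone marrow than in spleen. Cell makeup does not account for all of it, since the list's median was 0.52 over all cells and 0.36 in HSC-like cells. In HSC-like cells Fos, Jun and Fosb were called with the source term. The median was lower there than over all cells, so a part due to makeup was not excluded. Tissue preparation (crushing, digestion and time before the sort) cannot be told apart from tissue, because 0 sources had more than 1 preparation of a tissue. Splits of the 6 sums number 10, too few for a share under 0.05: the real split called 0 genes and the highest other 10 over all cells, and 0 and 9 in HSC-like cells. With the source term it called 1 against 0, and 7 against 0 in HSC-like cells, among the 4 splits that part every pair. A difference between niches stays open and was not tested.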

How the results depend on the processing

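Settings that correct hashtags for background, or that join HSC-like cells with a source term or a match in UMIs, were chosen after the data were seen. The cause of the changes below was not tested except where named.

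Bone marrow against spleen, main count 0: the count stayed 0 under 15 settings and was 12 with DESeq2, 1 with the source term, 7 with HSC-like cells and the source term, 6 with corrected hashtags and the source term, and 4 with all of these; leaving out 1 source gave 0 to 41. tdTomato-positive against negative cells, main count 0: it stayed 0 under 21 settings, and was 114 with DESeq2, 34 with no filter on low counts, 326 with the pup term, 264 with the tube as a block, 74 with HSC-like cells, 375 with these and the pup term, 9 with these, the pup term and matched UMIs, 550 with corrected hashtags and the pup term, and 428 with HSC-like cells as well, but 0 when the UMI match was added to that last setting (317 at an unadjusted p under 0.05); leaving out 1 sum gave 0 to 385. Tppp3-detected against undetected cells, main count 0: it stayed 0 under 6 settings and was 14 with DESeq2, 251 with no filter, 45 with the source term, 4 with all undetected cells, 86 with HSC-like cells (and 86 with the source term, which there is the batch term and gives the same fit), 1 with the stricter hashtag ratio, and 2, 65, 73 and 146 with corrected hashtags alone, with HSC-like cells, with the source term and with both; leaving out 1 source gave 0 to 52. The source term takes out differences between sources that otherwise count as error. On simulated 2-fold changes it raised recovery over all cells from 28 to 92 of 100 genes for tissue, and false calls from 0 to 14. In HSC-like cells, where the 7 tissue genes were called, it raised recovery only from 98 to 100 and false calls from 1 to 14. These false calls came beside the planted changes that were recovered, so their number does not carry over to the 7 genes.

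Of 33 lists called by camera, 0 were called with an estimated correlation and 1 with fry; with the source term, HSC-like cells or both, 38, 25 and 26 were. Over all cells the source term added platelet-biased HSC and megakaryocyte genes (adjusted p = 0.0333) and immediate early genes (adjusted p = 0.00682) to the tdTomato lists, both with adjusted p = 0.767 with an estimated correlation. It added myeloid progenitor (adjusted p = 0.00259), oxidative phosphorylation (adjusted p = 0.023) and hepatocyte genes (adjusted p = 0.0197, 1 gene measured) to the Tppp3 lists, with adjusted p = 0.385, 0.633 and 0.256 with an estimated correlation.

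HSC-like shares with resolution halved, doubled or without cell-cycle genes were 26.2%, 26.0% and 25.6% in pooled bone marrow, 3.59%, 4.67% and 4.48% in liver and 18.1%, 20.9% and 19.0% in spleen, and 97.4% in pup 2 with resolution doubled; other shares stayed within their intervals. Tppp3 shares of all cells at 5000 UMIs, without thinning and at 2500 UMIs were 0.208%, 0.359% and 0.103% at E19, 0.770%, 1.70% and 0.297% in pup 1, and 0.494%, 2.25% and 0.638% in pup 2. S or G2/M shares of all cells, without thinning and at 2500 UMIs, were 64.2% and 65.5% in spleen, 37.6% and 36.9% at E19, 63.3% and 62.4% in pup 2, and 75.5% without thinning in pooled bone marrow.

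Liver genes beyond 2-fold numbered 104, and 12 in HSC-like cells (9 with TMM), 0 of them shared with the 104; other cell filters and TMM gave 99 to 107. E19 genes numbered 47 and 41 to 61 under 5 settings. The bone marrow minus spleen difference in S or G2/M share of the pool reversed, from −1.51 points to 6.71 at 2500 UMIs and 11.3 without thinning, and G2/M genes at E19 against the pooled tissues reversed from −0.43 or lower over all cells to 1.09 or higher in HSC-like cells. So did its interferon genes against the same tissues (0.14 to 0.27 over all cells, −0.62 or lower in HSC-like cells) and, against pup 1 bone marrow, its quiescence genes (−0.33 and 0.39). In pup 1 the bone marrow minus spleen difference in Tppp3 share of all cells reversed, from 0.375 points to −0.351 at 2500 UMIs. The source term changed no call of a gene list in HSC-like cells of the tissue comparison. The number of cells limits the Tppp3 shares of tdTomato-positive cells, where 0 of 29 and 0 of 39 have exact upper limits of 11.9% and 9.03%.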

Other observations

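These tests were chosen only after the results were seen. A hypothesis was that the labelled lineage and cells that express Tppp3 at the time of sampling share expression. Of 177 genes with p under 0.01 for Tppp3 detection in HSC-like cells of the pool and E19 alone, 90.4% (160 genes) went the same way in the tdTomato contrast of the pups, against 50.3% in a contrast of the tubes over the same sums. Without cell-cycle genes these were 89.7% and 47.3%. With the tdTomato-negative cells nearest in total UMIs, a match that held in pup 2 only, the share was 75.7%, but the tube contrast of the matched sums lay as far from an even share, at 25.4%, so total UMIs per cell cannot be told apart from shared expression as a source of the overlap, although the bound set for that test was met. With hashtags corrected for background the shares were 88.7% and 32.2%, and with these and the UMI match 78.0% and 10.2%, where the tube contrast lay further from an even share than the tdTomato contrast. The genes are not independent replicates, and over all genes the correlation across genes of the 2 contrasts was 0.251. It was 0.0718 with the UMI match and 0.115 with corrected hashtags and the match, where the tube contrasts gave −0.145 and −0.247. Shared expression may account for part of the overlap, and the matched sums leave that open.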
